A study of Mus musculus with 8 samples.

How the data were processed

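Acetylated RNA immunoprecipitation sequencing (acRIP-seq) was done on bone marrow-derived monocytes of WT and Nat10 CKO mice after 3 days of RANKL. Total RNA was fragmented, incubated with an anti-ac4C antibody and captured on protein A/G beads, and IP and input libraries were sequenced as paired-end reads on an Illumina NovaSeq, per the labels' protocols. There were 4 IP and 4 input samples. Each of the 4 deposited files is a peak list whose file name and peak names carry the library code found in the titles of 1 IP sample and its input; the genotype was taken from those samples' labels. Replicates 1 and 2 of a genotype are separate samples per the titles, but nothing says whether they came from separate mice or cultures. The permutation p-values therefore measure only the spread between these lists, which may be technical. Fisher's exact tests were run over regions and measure no spread between lists.

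The submitters' processing notes name fastp 0.20.1, STAR 2.7.8a and MACS2 2.2.7.1 and the build mm39 (GRCm39). Per the labels' description the lists are MACS2 peaks of IP against input, and the peak names show that they were called per library, not on pooled samples. The files have no header and 6 columns (chromosome, start, end, peak name, score, strand). The deposited score of each peak is the authors' own value; which MACS2 quantity it is and how peaks were restricted to mRNA and given a strand are not given in the sources used here. In the authors' deposited table the lowest score is 5.01 (WT 1), 5.03 (WT 2), 5.0 (CKO 1) and 5.0 (CKO 2), so weaker peaks were left out. The median score differs between the lists (72.3, 29.5, 71.3 and 116.5 in the authors' deposited table, in the same order), and since each list was called separately, scores were used only to rank peaks within a list. Peak names run to 61914, 39584, 60022 and 45960 in the same order. The number of peaks in each list comes to 45.3%, 62.8%, 46.8% and 52.8% of that highest number, so part of each original call set is not in these lists. The files hold no read totals: the depth is unknown and no interval for a single peak can be given. Positions were read as BED, which counts from 0, because 200 bases is the most frequent end minus start in every list, and are printed counting from 1.

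No genome was given for mm39. The gene table at hand is of GRCm38.p6, and only 58.8% to 59.6% of the peaks of a list, which should lie in mRNA, fell inside its protein-coding gene spans (47.1% to 47.7% after moving the peaks by 1000000 bases), so the builds differ and its coordinates were not used. For this reason the planned gene-level comparisons (genes lost and gained, fixed gene lists of osteoclast, macrophage, lysosome, translation and other functions, markers of other cell types), the position of peaks in UTRs and coding sequence, and the cytosine content and CXX motifs of peak sequences were not run. The rule for named genes, fixed before the data were examined, was applied to regions instead: the 10 lost, the 10 gained and the 5 shared regions with the highest mean within-list rank percentile of their best peak. The parts of that rule on Nfatc1, Nat10 and list members need gene names and were not applied.

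Peaks of the 4 lists were merged into regions where they shared at least 1 base on the same strand; a region was lost if both WT lists and neither CKO list held a peak in it, and gained in the opposite case. The deposited lists give only part of the called peaks. An absent peak thus means a signal under the authors' threshold or a call left out of the list, not absence of ac4C. Overlap of lists was measured by the Jaccard index of bases, within and across genotypes, and against lists moved by 5000 bases. Group values were compared by exact two-sided permutation over the 3 splits of the 4 lists into pairs, whose smallest p is 0.333, with Benjamini-Hochberg adjustment over the 8 comparisons. Counts of lost and gained regions were set beside those under the other 2 splits, and shares of regions have 95% Wilson intervals. The merge was tested on simulated lists with known answers. In 100 simulated sets of the 75389 regions with no genotype effect, the genotype total exceeded both other splits in 6; with 200 planted losses it did so in 73, and with 400 in all 100. The lost count itself was 3012 ± 45.8 (SD over the 100 sets) with no effect and 3200 ± 51.2 with 200 planted losses. Whether it exceeds every other pair of lists says little in these sets: it did so in 0 of 100 with no effect and with 50, 100 or 200 planted losses, in 1 with 400 and in all 100 with 800, because WT 1 with CKO 1, the largest lists, has the highest number expected from list sizes (3611 against 3006). These sets assume that lists differ only in size. The real lists depart from this: WT 1 with CKO 1 lay at -11.5% and WT 2 with CKO 2 at 10.1% from their size-based numbers. The simulated rates and counts therefore need not hold for the real lists. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.

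Alternatives fixed before the data were examined were the top 50% of each list by score, equal numbers of peaks per list, an overlap of at least 50% of the shorter peak, merging across gaps of up to 100 bases, leaving out each list, and comparison within replicate numbers, the last 2 for overlap and for lost and gained regions. For the number of peaks per list, leaving out each list and comparison within replicate numbers were added after the data had been seen, as were chaining into loci across 5000 bases and keeping only peaks of 200 bases or more. The replicate numbers are shared by the genotypes, but the labels give no common mouse, day or batch. The correlation over regions between the WT difference (list 1 minus list 2) and the CKO difference was -0.008. This is a weak test of pairing, because 69.13% of regions were held by 1 list, where 1 of these differences is 0. Peak numbers did follow the replicate number: 28065 (WT) and 28087 (CKO) in lists 1, and 24851 and 24249 in lists 2. With no tie in the labels the numbers were not taken to pair the samples, but a shared batch cannot be excluded.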

Results

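N4-acetylcytidine (ac4C), an acetylated form of cytosine in RNA, was mapped in bone marrow-derived monocytes that had been driven towards osteoclasts, the bone-resorbing cells of the monocyte lineage, with RANKL (receptor activator of NF-kB ligand) for 3 days. The cells came from wild-type (WT) mice and from mice with a conditional knockout (CKO) of Nat10, which encodes the RNA cytidine acetyltransferase that writes ac4C. The study asked, per its design text, how loss of this enzyme changes ac4C during osteoclast formation. Fragmented RNA was precipitated with an ac4C antibody (IP) and sequenced beside an input portion, giving 8 samples (4 IP and 4 input) that were reduced by the authors to 4 peak lists, 2 per genotype. Each list gives the positions in mRNA where 1 IP library stood above its own input. The lists carry positions but no gene names and no read counts, so regions are named below by chromosome and base position in mm39, the sequencing depth behind each peak is unknown, and Nat10 and Nfatc1 were not located here.

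The WT and CKO lists held about as many called peaks. Each list was called separately and its depth is unknown, so these counts do not measure the amount of ac4C. Loss of Nat10 in the cells could not be checked in these lists. The 2 WT lists held 28065 and 24851 peaks and the 2 CKO lists held 28087 and 24249. The group means were 26458 ± 2273 peaks in WT and 26168 ± 2714 in CKO (SD, n = 2 each), so the CKO mean was lower by 290 peaks, far less than the spread between lists of a genotype. An exact two-sided permutation test gave p = 1.0 (adjusted p = 1.0 over 8 comparisons of this kind), and with 2 lists against 2 such a test cannot go below 0.333. The CKO mean was higher than the WT mean, by 1317 or 1629 peaks, when WT list 1 or CKO list 2 was left out. Peaks covered 3.56 ± 0.03 Mb in WT and 3.47 ± 0.27 Mb in CKO (SD, n = 2 each). Their median width was 113 and 110 bases in the WT lists and 115 and 120 bases in the CKO lists. This was the only one of the 7 list measures tested in which the genotypes did not overlap, and its exact two-sided p was 0.333 (adjusted p = 1.0).

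Autosomes and the X chromosome carried similar shares of the peaks in all 4 lists. Chromosome 11 held 8.27% and 7.85% of the WT peaks and 8.53% and 8.62% of the CKO peaks, and the X chromosome held 2.57% and 2.91% of the WT peaks and 2.39% and 2.47% of the CKO peaks. The shares of the 2 genotypes did not overlap on 7 of these 20 chromosomes. Chance gives this for 33.3% of chromosomes, and regrouping the lists as WT 1 with CKO 1 or WT 1 with CKO 2 gave 4 and 8 chromosomes.

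On the mitochondrial chromosome, 10 regions were called, of which 4 carried a peak in all 4 lists. These 4 lay on the plus strand at bases 2790 to 3696, 5397 to 5752, 12659 to 13565 and 14195 to 15147. The WT lists held 8 and 7 mitochondrial peaks and the CKO lists 11 and 9. Both CKO lists had a peak in 9 of the 10 regions and both WT lists in 4. This difference was not tested, and with 2 lists against 2 no exact p below 0.333 can be reached. The region at bases 3976 to 4894 had a peak in both CKO lists and in neither WT list, and no mitochondrial region was held by both WT lists alone. Neither the peak numbers nor this 1 region can settle whether the genotypes differ here. Peak numbers of 2 lists against 2 fail to overlap by chance in 33.3% of cases. In both CKO lists alone were 1 of 10 mitochondrial regions and 3.63% of the nuclear regions (2740 of 75379). The two-sided Fisher's exact p of 0.31 for these shares compares mitochondrial with nuclear regions, not the genotypes. With 10 mitochondrial regions it decides little. The only minus-strand region, at bases 13709 to 14022, was called in WT list 1 alone.

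**Figure D1:**
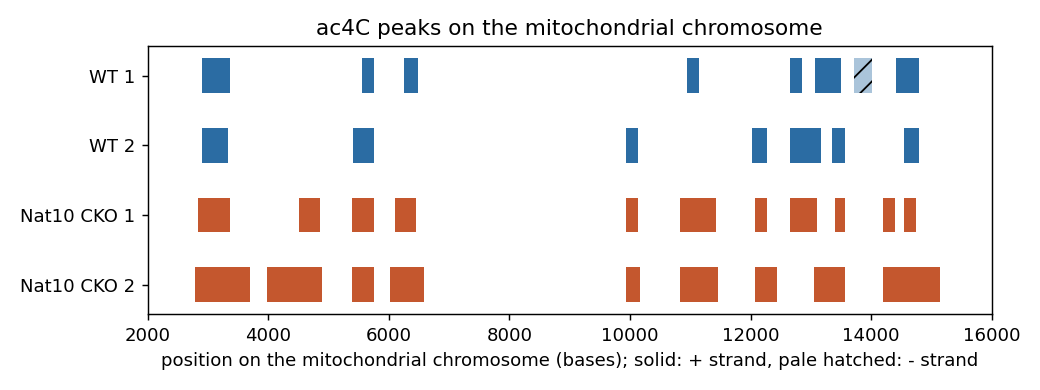
Peaks on the mitochondrial chromosome, by position in bases (x axis) and list (rows); each bar is 1 peak at its true length, solid on the plus strand and pale hatched on the minus strand. The WT lists hold 8 and 7 peaks and the CKO lists 11 and 9, and 4 regions carry a peak in every list.

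On average, replicate lists of a genotype did not share more of their called peak positions than lists of different genotypes did. The Jaccard index, shared bases over all bases covered by a pair of lists on the same strand, was 0.0983 for the 2 WT lists and 0.0899 for the 2 CKO lists. Across genotypes it was 0.0932 (WT 1 with CKO 1), 0.0917 (WT 1 with CKO 2), 0.0992 (WT 2 with CKO 1) and 0.0938 (WT 2 with CKO 2). The mean within a genotype was 0.0941, against 0.0945 ± 0.0033 across genotypes (SD over the 4 pairs), a difference of -0.0004. The exact permutation test over the 3 ways to part 4 lists into pairs gave a one-sided p of 0.667 for a higher overlap within genotypes. The difference changed sign when either CKO list was left out, to 0.0056 without CKO list 1 and 0.0021 without CKO list 2. With 1 list of a pair moved along the genome by 5000 bases the index was 0.0035 to 0.005. Because the lists hold only peaks in mRNA, such a move can take peaks out of the exons, so these values are no measure of chance overlap within mRNA. Of the peaks of a list, 20.4% to 25.2% had a partner in any 1 other list.

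**Figure D2:**
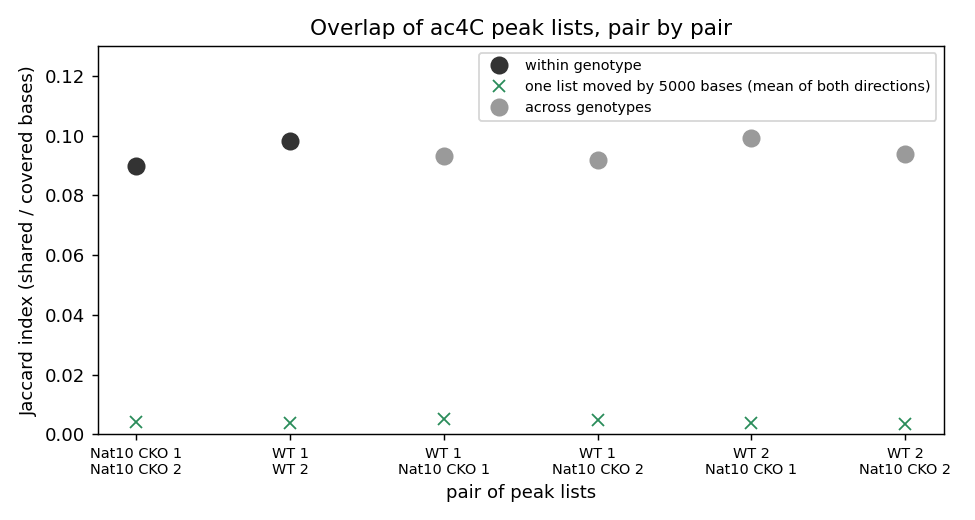
Jaccard index (y axis, shared over covered bases) for the 6 pairs of peak lists (x axis); dark points are pairs of 1 genotype, grey points pairs across genotypes, and green crosses the same pair with 1 list moved by 5000 bases. The 2 within-genotype pairs, at 0.0983 and 0.0899, lie among or below the 4 cross-genotype pairs, at 0.0917 to 0.0992.

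Merging the 4 lists on any same-strand overlap gave 75389 regions, of which 52115 (69.13%) carried a peak in 1 list, 17842 in 2 lists, 4705 in 3 lists and 727 (0.96%) in all 4. The regions held by all 4 lists had a median length of 221 bases, against 110 bases for those of 1 list only; a merged region spans all of its peaks, so its length rises with the number of lists by construction. The 5 strongest of these shared regions, by the mean rank of their authors' scores within each list, stood on chromosome 5 minus strand at bases 142890282 to 142890537 and 142891105 to 142891231, on chromosome 8 minus strand at 123151637 to 123151826, on chromosome 19 plus strand at 9961545 to 9961584, and on chromosome 9 plus strand at 40715461 to 40715659. Each stood at percentile 99.82 or higher in every list. The share of peaks that no other list held was 50.7% and 46.8% in WT and 51.6% and 48.5% in CKO.

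Peaks held by both WT lists and absent from both CKO lists, called lost here, numbered 3210, and those held by both CKO lists and absent from both WT lists, called gained, numbered 2741. Lost regions made up 51.0% of the 6299 regions present in both WT lists (95% Wilson interval 49.73 to 52.19), and gained regions 47.2% of the 5811 present in both CKO lists (45.89 to 48.45). These intervals cover counting error over regions only. The lost count was the highest of the 6 pairs of lists, by 13 regions over the highest pair that mixed the genotypes, and the gained count lay within the range of the mixed pairs: 3197 regions were held by WT 1 and CKO 1 alone, 2660 by WT 2 and CKO 2, 2898 by WT 1 and CKO 2, and 3136 by WT 2 and CKO 1. In both directions together the genotype split gave 5951 regions and the other splits 5857 and 6034, so the genotype came between the splits that mix it. Of the 17842 regions held by exactly 2 lists, 33.4% (95% Wilson interval 32.7 to 34.0) were held by lists of the same genotype, and the sizes of the lists alone give 33.1%. From list sizes alone, 3006 lost and 2901 gained regions would be held, and 3611 by WT 1 and CKO 1; the lost count departed from this by 6.8% and the gained count by -5.5%. The mixed pairs departed from their own size-based numbers by -11.5% (WT 1 with CKO 1) to 10.1% (WT 2 with CKO 2). The lost count rested on both WT lists: with WT list 1 or WT list 2 left out, a single WT list sets the count and it came to 14886 or 17632. Without CKO list 1 or 2 the gained count came to 14575 or 17356.

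**Figure D3:**
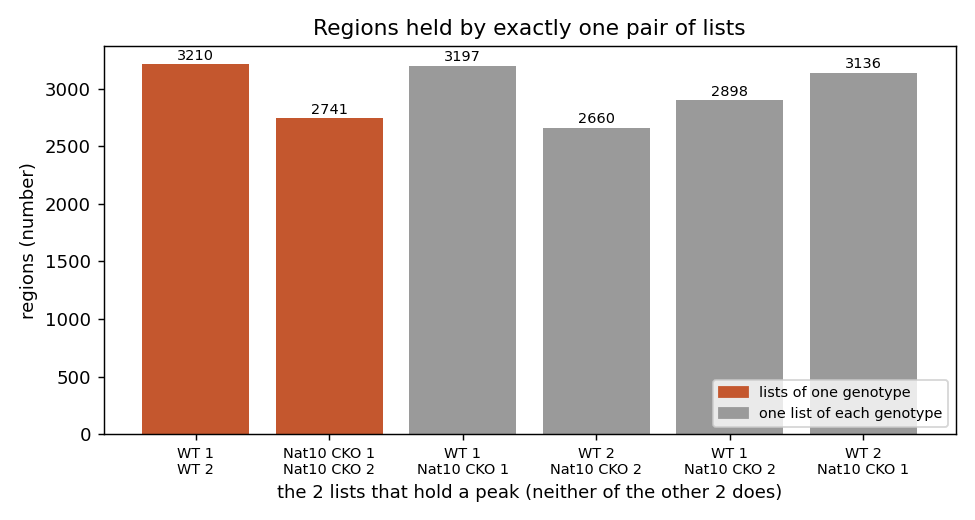
Number of regions (y axis, from 0) held by exactly 1 pair of lists (x axis); orange bars are pairs of 1 genotype (lost, 3210; gained, 2741) and grey bars pairs with 1 list of each genotype. The mixed pairs range from 2660 to 3197; the lost count lies just above and the gained count within that range.

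Among the lost regions, the 10 strongest by rank lay on 8 chromosomes. The highest ranked was on chromosome 10 minus strand at bases 117113756 to 117114092, where the peak stood at percentile 99.99 of WT list 1 and 100.0 of WT list 2 and the nearest CKO peak on that strand was 9660 bases away. With peaks under 200 bases left out, it had a peak in only 1 WT list. On chromosome 17 minus strand, regions were lost at 45880166 to 45880313 and at 45881592 to 45881653. The others were on chromosome X at 9302947 to 9303202, chromosome 15 at 83038336 to 83038594, chromosome 10 at 51371312 to 51371602, chromosome 6 at 29467751 to 29467952, chromosome 11 at 120238573 to 120238701, chromosome 2 at 129473733 to 129473955 and chromosome 12 at 51838020 to 51838222. The chromosome 11 region had no CKO peak within 22821 bases. The region of chromosome 17 starting at 45880166, in contrast, had a CKO peak 113 bases away.

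Among the gained regions, the highest ranked was on chromosome 11 minus strand at bases 69556846 to 69556909, at percentile 99.98 of CKO list 1 and 99.88 of CKO list 2, with a WT peak 83 bases away. Merged across gaps of up to 100 bases, it carried peaks of both genotypes and was no longer gained. Gained regions on chromosome 5 plus strand at 90622426 to 90622537 and 90623128 to 90623184 lay beside each other. The chromosome 5 minus-strand region at 142889822 to 142890003 lay 125 bases from the nearest WT peak and in the same stretch as the strongest region shared by all lists. The chromosome 10 region at 51370980 to 51370989, gained, and the region at 51371312 to 51371602, lost, were 322 bases apart on the same strand. This gained region was 10 bases long. Whether the score of such a short peak belongs to a longer peak cut down to mRNA is not given in the sources used here. The others were on chromosome 3 at 82949555 to 82949941 and 98204286 to 98204410, chromosome 1 at 62822453 to 62822707, chromosome 9 at 106308268 to 106308673, and chromosome 4 at 49543714 to 49543868. The nearest WT peak to the chromosome 9 region was 19918 bases away, and to the chromosome 1 region 11561 bases.

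Most lost and gained regions lay in stretches that the other genotype also marked. To see this, a grouping chosen after the regions had been seen chained same-strand peaks of any list across gaps of up to 5000 bases into 27045 loci. Of the 3210 lost regions, 2362 (73.6%) lay in a locus with a CKO peak, and of the 2741 gained regions, 2193 (80.0%) lay in a locus with a WT peak. For the pairs that mixed the genotypes the corresponding shares were 73.5% to 80.0%. Of the named regions, 8 of the 10 lost and 8 of the 10 gained lay in such loci. At this scale 1263 loci had peaks in both WT lists alone and 1026 in both CKO lists alone, against 977 to 1276 for the mixed pairs.

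Some loci differed in peak number between the genotypes in every list. The widest gap was on chromosome 9 plus strand at bases 67793586 to 67865018, with 15 and 13 peaks in the WT lists and 5 and 6 in the CKO lists. This stretch held 29 separate regions, of which 5 were in both WT lists alone and 0 were in all 4 lists. It also held regions in both CKO lists alone, starting at bases 67810841 and 67834644. On the X chromosome at 47361677 to 47371099 each WT list held 4 peaks and each CKO list 0, and on chromosome 5 minus strand at 125501359 to 125508830 the WT lists held 5 each and the CKO lists 1 and 0. In the other direction, chromosome 9 minus strand at 85202572 to 85209055 held 2 and 1 WT peaks and 7 in each CKO list, and chromosome 11 minus strand at 120699117 to 120714606 held 1 in each WT list and 6 in each CKO list. Loci in which every list of a genotype exceeded every list of the other by 3 peaks or more numbered 91 (32 higher in WT and 59 higher in CKO). The other splits gave 102 and 90 such loci, so these loci, picked for their gap, were no more frequent than regrouped lists produce.

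**Figure D4:**
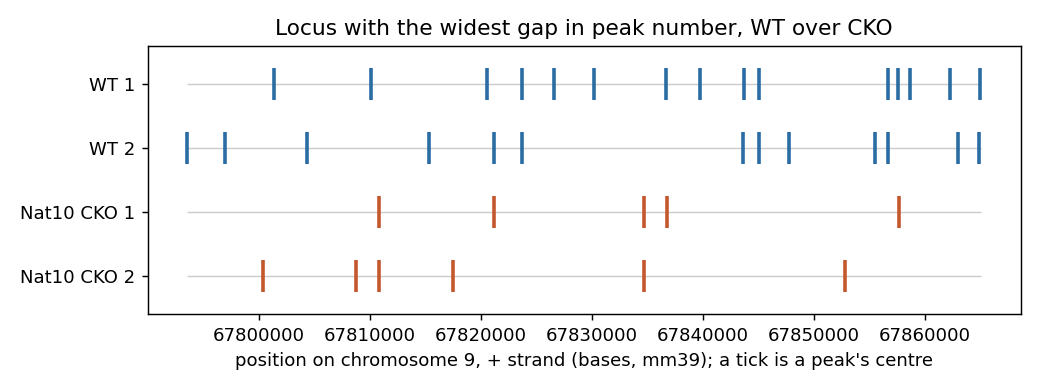
Peak centres along chromosome 9 plus strand, bases 67793586 to 67865018 (x axis, mm39), for the 4 lists (rows), in the locus with the widest gap in peak number, chosen for that gap. The WT lists hold 15 and 13 peaks and the CKO lists 5 and 6.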

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

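The within-minus-across difference was -0.0004 as reported, -0.0004 with equal numbers of peaks and -0.0011 with peaks of 200 bases or more, and it changed sign to 0.0001 for the top 50% of each list and to 0.0002 for the share of peaks with a partner covering 50% of the shorter peak. Leaving out 1 list gave -0.0066 (without WT 1) to 0.0056 (without CKO 1, where the WT pair, at 0.0983, exceeded the remaining cross-genotype pairs, at 0.0917 and 0.0938). The replicate block, which uses only cross-genotype pairs of the same number, gave 0.0006. For peak number, leaving out 1 list gave differences of -2209 to 1629, and the blocked difference was -290, the mean of 22 and -602. The lost count moved from 3210 to 1397 in the top 50% of each list, to 1263 as loci chained across 5000 bases and to 828 for peaks of 200 bases or more; the gained count moved from 2741 to 1027, 1026 and 903. With fewer peaks or fewer, wider units, fewer regions can be counted. Leaving out 1 list gave 4270 to 17632 lost and 3769 to 17356 gained regions, because a single list then stands for its genotype. Counted within replicate numbers (paired), 20344 regions were lost and 20051 gained on average, again because 1 list stands for each genotype. Over the 7 settings that keep all 4 lists, the lost count exceeded the gained count except for peaks of 200 bases or more. The lost count was the highest of the 6 pairs of lists in 4 of these 7 settings (3210 against 3197 for the highest mixed pair, 1397 against 1355, 2896 against 2836 and 3149 against 3101) and not in the other 3. The genotype split gave the highest total of the 3 splits in 1 of 7 settings, the loci, by 2289 against 2285. Of the 25 named regions, the top 50%, equal numbers and 50% overlap settings left each in its class. For the top 50% and equal numbers this was fixed in advance and shows no stability. Those settings drop only lower-scored peaks, and the named regions were picked for their high ranks. Merging across 100 bases moved only the highest-ranked gained region, on chromosome 11. Among peaks of 200 bases or more, 6 of 7 lost, 2 of 2 gained and 1 of 1 shared regions that could be measured kept their class, and the exception was the highest-ranked lost region, on chromosome 10, which then had a peak in 1 WT list. As loci, 2 of 10 lost and 2 of 10 gained regions kept their class. The planned settings for gene lists, mRNA position and sequence were not run, for want of an mm39 annotation. The unknown read depth limits all of this: an absent peak cannot be told from an undersampled one.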

Other observations

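The tests of peak strength, short fragments and peak offsets below were set out before their results were seen; the others were chosen after.

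Most regions (69.13%) were called in 1 list only, and 46.8% to 51.6% of the peaks of a list were found in no other list. What part the genotype had in this stays open. The Jaccard index within genotypes minus that across was -0.0004, between the values of the other splits (-0.0013 and 0.0016), and it changed sign in 5 of the 9 other settings. The 2 CKO lists, at 0.0899, overlapped less than any cross-genotype pair, and the 2 WT lists, at 0.0983, more than 3 of the 4. With 3 splits no p below 0.333 can be reached. Weak peaks were not the whole reason, since among the top 10% of each list by score 28.2% to 37.1% had a partner in the other list of the genotype, more than over all peaks but below 50% in every list. Short fragments at the ends of mRNA exons were not either: of the peaks of 200 bases or more at most 28.5% had such a partner, and allowing an offset of 100 bases raised the share for all peaks to 26.5% at most. Undersampling of most transcripts in each library may remain, as may differences between cultures or mice, and neither can be tested without read counts.

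WT list 2 stood apart in its peak widths. Of its peaks, 6.51% were exactly 200 bases wide (95% Wilson interval 6.21 to 6.82), against 24.07%, 24.01% and 24.44% in WT 1, CKO 1 and CKO 2, while 22.2% were wider than 200 bases, against 9.55%, 10.35% and 10.64%. A different minimum peak length is argued against by the most frequent width, which was 200 bases in that list as well. Lower sequencing depth of that library may contribute but cannot be told apart from other causes, because depth is not in the lists; its peak names ran to 39584, the lowest of the 4. No biological explanation was tested, since the other WT list did not share the pattern. Among regions held by exactly 2 lists, the pairs with WT 2 exceeded the number that list sizes give, by 6.8% with WT 1, 4.2% with CKO 1 and 10.1% with CKO 2, so the largest excess was with a list of the other genotype.

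Peaks recurred more often on the mitochondrial chromosome, where 4 of 10 regions (40%, 95% Wilson interval 16.82 to 68.73) were held by all 4 lists, than on the nuclear chromosomes, where 723 of 75379 (0.96%) were, with a two-sided Fisher's exact p of 1.7e-06 over regions. The greater width of the mitochondrial peaks is argued against as the whole reason. In each list, 44.4% to 71.4% of the 7 to 11 mitochondrial peaks had a partner in all 3 other lists (lowest 95% Wilson bound 18.88%), against at most 11.4% of the nuclear peaks at least as wide as that list's median mitochondrial peak (highest bound 17.9%). The closer spacing of peaks on this small chromosome and the abundance of its RNAs may also raise the overlap, and neither was tested.

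The hypothesis that loci carried several more peaks in 1 genotype was tested by a count. It took loci in which every list of a genotype exceeded every list of the other by 3 peaks or more. Such loci can hold peaks of both genotypes. The genotype split gave 91 and the others 102 and 90, so the count does not set the genotype apart. Loci with peaks in both lists of 1 side and in neither list of the other numbered 2289 under the genotype split. The other splits gave 2228 and 2285 of these. With 3 splits no p below 0.333 can be reached. Single loci such as chromosome 9 at 67793586 to 67865018, with 15 and 13 WT peaks against 5 and 6, remain places to examine with read counts. On the Y chromosome, WT list 2 and CKO list 2 held 1 peak each and the other lists 0.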
